A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

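Ribosome profiling, which sequences the stretches of mRNA protected by ribosomes, was carried out on 2 SK1 yeast cultures, 1 wild type and 1 lacking GIM3. Per the labels' protocols, cells were grown in YEPD for 24 hours at 22 degrees C, then in BYTA for 16 hours, washed and moved to sporulation medium, and were flash frozen and milled in the cold with lysis buffer. The libraries were taken after 4 hours in that medium. Both libraries hold footprints, and no matched mRNA libraries were used here, so a difference in footprints cannot be divided into mRNA level and translation.

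The authors deposited 1 table with a value per gene and library. The unit was found from the values, since the file headers give only time and genotype. Each column sums to 1000000, so the values the authors deposited are RPM, reads scaled to a library total of 1000000, and they are not divided by gene length. Every value (100% in both libraries, within 0.001 of a read) was a whole multiple of the smallest one, so that read numbers could be recovered exactly: 40433177 for wild type, where 1 read is 0.0247 RPM, and 27864644 for gim3 deletion, where 1 read is 0.0359 RPM. Per the submitters' processing notes, Bowtie2, STAR and SAMtools were used. Their versions and roles, the genome build, the annotation, the treatment of reads that match several places and the positions at the ends of genes that may have been left out are not given in the sources used here. Reads shared between near-identical genes may therefore be split or lost, and overlapping genes may share reads. Of the 6678 lines of the table, 86 carried no gene name. They held 0.121% of the wild-type reads and 0.124% of the gim3 deletion reads, and they were left out of all comparisons but kept in the deposited scaling. Gene names are those of the file. They were matched to the symbols, locus tags and synonyms of the R64 RefSeq table for 5910 of 6592 names, and for 4884 of the 4916 compared genes (99.3%). That table gave the order of genes around GIM3 and gene lengths with introns, and showed which named genes overlap another.

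From these values the log2 ratio of gim3 deletion over wild type was computed after adding a pseudocount of 1 RPM, which understates the difference of low genes. Folds are ratios of RPM with no pseudocount, with exact (Clopper-Pearson) 95% intervals from the division of a gene's reads between the libraries. PCR duplicates cannot be told from separate molecules here, so these intervals cover counting error only. Genes were compared where the mean of both libraries was at least 10 RPM (4916 genes). With 1 library per genotype, differences were counted by a fixed rule of size, at least 2-fold on the log2 scale with the pseudocount. Gene lists were written before the data were examined. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size with the same number of genes from each of 20 bins of mean level. That percentile describes these 2 libraries and is no test between genotypes. Of the 32 lists, 31 had at least 3 measured members. The medians of 7 lay above the 97.5th percentile and of 5 below the 2.5th, where chance alone would place 1.55 lists in all. Named genes followed a rule fixed before the data were examined: a set of named regulators and prefoldin, tubulin and marker genes, the 12 genes with the highest and the 12 with the lowest ratio, and the highest and lowest member of each list. Some of the genes this rule names are not reported here. Further list members are given as examples and were chosen after their values were seen, as were 8 further lists described in the closing section.

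The count test that fits recovered reads, a negative binomial model, needs replicates and was not run. An exact binomial test per gene was run in its place as a comparison of the 2 libraries alone. On simulated libraries of the same depth with 6592 genes, the 2-fold rule called 47 of 50 genes changed 3-fold, 50 of 50 changed 4-fold, 47 of 50 changed 8-fold, 0 of 50 changed 1.5-fold and 0 of 4705 unchanged genes. The simulation held counting error only and no variation between cultures. Alternatives covered the pseudocount, the filter, the scaling (centring on the median gene, a trimmed mean that leaves out 30% of ratios and 5% of levels at each end, totals without ribosomal protein genes or without the middle meiotic list), trends on gene length and on level (lowess, fraction 0.5), the threshold, the mean in place of the median, and unmatched random lists. A list median was taken as moved when an alternative left the 95% range of 2000 bootstrap draws over the list's genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.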

Results

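Ribosome footprints were sequenced from 2 budding yeast cultures of the SK1 background, a strain that enters meiosis efficiently when starved. The cells had spent 4 hours in sporulation medium, which triggers meiosis. One culture was wild type and the other lacked GIM3, which encodes a subunit of prefoldin, the cochaperone that hands unfolded actin and tubulin to the CCT chaperonin. There was 1 library per genotype and so no replicate error. Differences are therefore given as values of these 2 libraries with exact 95% intervals that cover counting error only, and no test between genotypes was possible. The wild-type library held 40433177 counted footprints and the gim3 deletion library 27864644, over 6592 named genes. The 4916 genes with a mean of at least 10 RPM (reads scaled to a library total of 1000000) were compared. Each had at least 588 reads over both libraries, and the upper end of the interval of the fold was 1.13 times the lower end for the median gene.

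GIM3 was almost without footprints in the library labelled gim3 deletion. It stood at 34.9 RPM in the wild-type library and at 0.108 in the gim3 deletion library, where the value came from 3 reads, a ratio of 325 (interval 111 to 1576). Of the other 5 prefoldin subunits, GIM5 differed most. It was 2.01-fold higher in the gim3 deletion library (1.90 to 2.13) and PFD1 1.29-fold higher (1.19 to 1.41). YKE2 had a ratio of 1.04 (0.942 to 1.15), whereas GIM4 was 1.25-fold lower (1.16 to 1.35) and PAC10 1.28-fold lower (1.18 to 1.40). On the chromosome, GIM3 lies between YCK2 and INN1. YCK2, a casein kinase I, was at 164 RPM in the wild-type library and at 760 in the gim3 deletion library, 4.64-fold higher (4.51 to 4.77). INN1, which acts in cytokinesis, was 2.22-fold lower (1.88 to 2.63).

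The first question the pair of libraries addresses is how far gene expression at the level of footprints differed between the genotypes at this time. Of the 4916 genes, 312 were at least 2-fold higher and 418 at least 2-fold lower in the gim3 deletion library, and 4186 (85.2%) lay within 2-fold. The median gene had a log2 ratio of -0.20 in the deposited scaling. Centring on that gene changed the split to 408 higher and 256 lower, so log2 ratios between -0.20 and 0, and ratios just below 1, turn to higher once centred. Across genes, which are not independent replicates, the log2 levels of the 2 libraries had a Pearson correlation of 0.89 and a Spearman correlation of 0.89. All 312 and 418 genes also differed by more than counting error in an exact two-sided binomial test on the recovered reads (Benjamini-Hochberg adjusted), but that test compares 2 libraries and not the genotypes, and it separated 4333 of the 4916 genes, 1478 higher and 2855 lower.

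**Figure D1:**
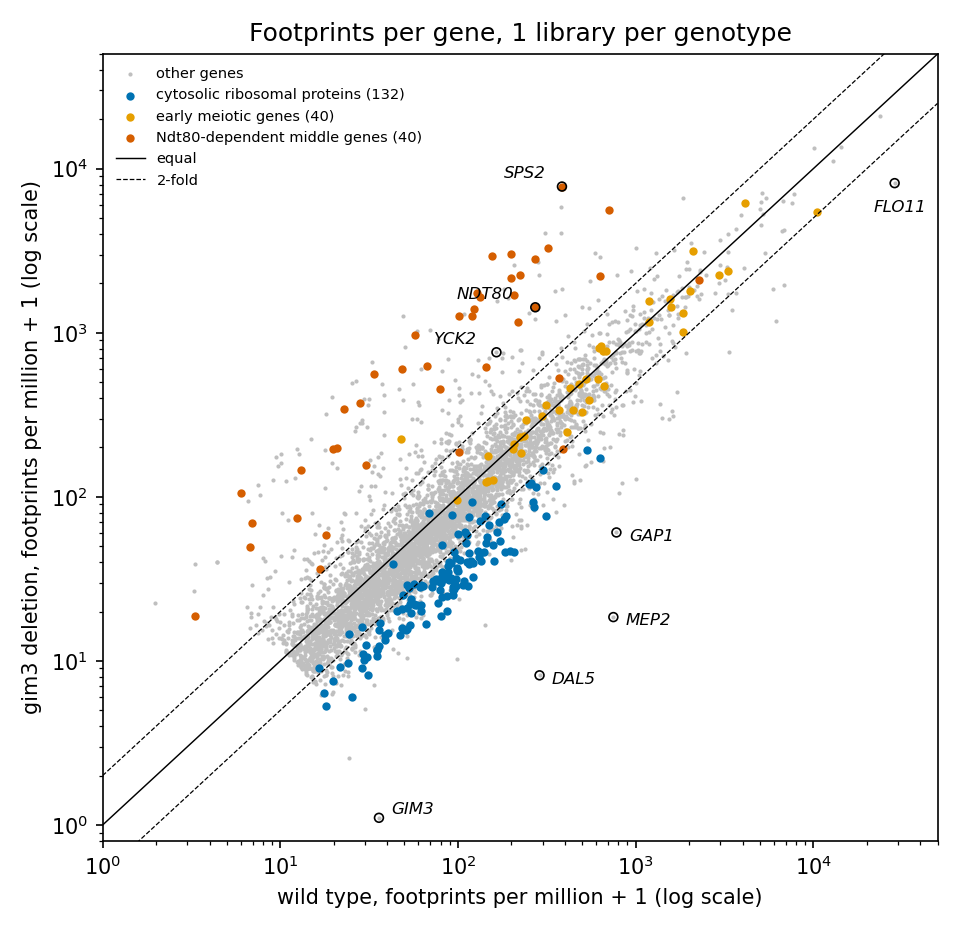
RPM of footprints plus 1 in the wild-type library (x axis) and in the gim3 deletion library (y axis), both on log scales, for the 4916 genes with a mean of at least 10. Each point is a gene, coloured by 3 of the gene lists, the solid line marks equal values and the dashed lines 2-fold; the Ndt80-dependent middle genes lie mostly above the upper dashed line and the cytosolic ribosomal protein genes mostly below the lower one.

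The 12 genes with the highest ratios included spore wall and spore membrane genes. GAS2, a glucanosyltransferase of the spore wall, was highest at 26.1-fold (24.9 to 27.3), from 48.2 to 1257 RPM. SPS2, which acts in spore wall assembly, went from 384 RPM in the wild-type library to 7784 in the gim3 deletion library, a 20.3-fold difference, and its relative SPS22 was 18.8-fold higher. SMA2, needed for the prospore membrane, was 20.8-fold higher and ISC10, required for sporulation, 20.7-fold. PFS1, which acts in prospore formation, was 20.8-fold higher and RRT12, a spore wall protease homologue, 17.8-fold. The other 5, YGL015C, PBI1, YFL040W, YBR063C and YGR273C, were between 18.7-fold and 21.7-fold higher.

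The 12 genes with the lowest ratios, GIM3 aside, were largely transporters and enzymes of nitrogen supply. MEP2, a high-affinity ammonium permease, had the lowest ratio, with 749 RPM in the wild-type library and 17.5 in the gim3 deletion library, 42.7-fold lower (39.1 to 46.8). DAL5, the allantoate permease, stood at 287 RPM in the wild-type library and 7.18 in the gim3 deletion library (ratio interval 34.8 to 46.2), and GAP1, the general amino acid permease, was 13.0-fold lower. The allantoin degradation genes DAL2 and DAL3 were 10.5-fold and 14.9-fold lower and DUR1,2, the urea amidolyase, 7.86-fold lower. DIP5, a permease for acidic amino acids, was 7.70-fold lower and MEP3, another ammonium permease, 7.01-fold lower. The glutamate dehydrogenases GDH3 and GDH1 were 6.97-fold and 5.23-fold lower, and because they are close paralogs the division of reads between them is uncertain. SCW4, a cell wall protein, was 9.02-fold lower and SIT1, a siderophore transporter, 5.30-fold lower.

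The second question was where the 2 libraries stood in the meiotic programme. Genes switched on by Ndt80, the transcription factor that starts the middle programme of meiotic divisions and spore formation, were higher in the gim3 deletion library almost throughout. Of 40 measured members of that list, 36 were at least 2-fold higher, 4 were within 2-fold and 0 were at least 2-fold lower. Their median log2 ratio was 3.32, a 9.95-fold difference, which 0 of 10000 random lists matched on expression reached. The list took 0.813% of all footprints in the wild-type library (Wilson 95% interval 0.810 to 0.816) and 5.24% in the gim3 deletion library (5.23 to 5.24). NDT80 itself was 5.26-fold higher (5.15 to 5.38). CDC5, the polo kinase, was 8.29-fold higher and the M-phase cyclins CLB1 and CLB4 were 17.1-fold and 5.82-fold higher, whereas CLB3 had few footprints in either library, 5.69 and 6.82 RPM. The highest member was SPS2 and the lowest AMA1, a meiotic activator of the anaphase-promoting complex, at 389 RPM in the wild-type library and 194 in the gim3 deletion library. With the pseudocount the log2 ratio of AMA1 was -0.997, just inside the 2-fold rule. FKS3, MPC54 and SPS19 were the other members within 2-fold, and 3 of the 43 listed genes were below the filter.

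Early meiotic genes, which act in the start of meiosis, recombination and pairing, showed no such shift. Of 40 measured members 39 were within 2-fold, and the list median was -0.04 in the deposited scaling and 0.17 above the median gene, at percentile 56.6 of the random lists. SPO11, which makes the meiotic double-strand breaks, had a ratio of 1.04 and ZIP1, of the synaptonemal complex, 1.04. DMC1, the meiotic recombinase, had a log2 ratio of -0.16, which turns to a positive value once centred. IME1, the master regulator of entry, was 1.37-fold lower (1.36 to 1.39), REC8, the meiotic cohesin subunit, was 1.41-fold lower, and IME2, a meiotic kinase, was higher with a log2 ratio of 0.59. RIM4, a translational repressor, was lowest at 1.92-fold lower. MAM1, a monopolin subunit, was the exception at 4.79-fold higher. The middle list lay 3.35 above the early list on the log2 scale, outside the central 95% of random pairs of lists (-0.34 to 0.27). DNA replication genes had a median of -0.54, 0.34 below the median gene and at percentile 0.030. Of their 31 members 4 were at least 2-fold lower and 0 higher, from RNR1, a ribonucleotide reductase subunit at 2.56-fold lower, to CLB5, an S-phase cyclin with a log2 ratio of 0.94. Late spore wall genes were mixed, with 3 of 9 at least 2-fold higher and 1 lower. DTR1, a dityrosine transporter, was 12.1-fold higher and SPS100 3.49-fold lower, and the list median of 0.52 was at percentile 99.6. That median was 1.81 with a filter at a mean of 50 and 0.35 after removing a trend on gene length, and the mean over the list was 1.16.

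**Figure D2:**
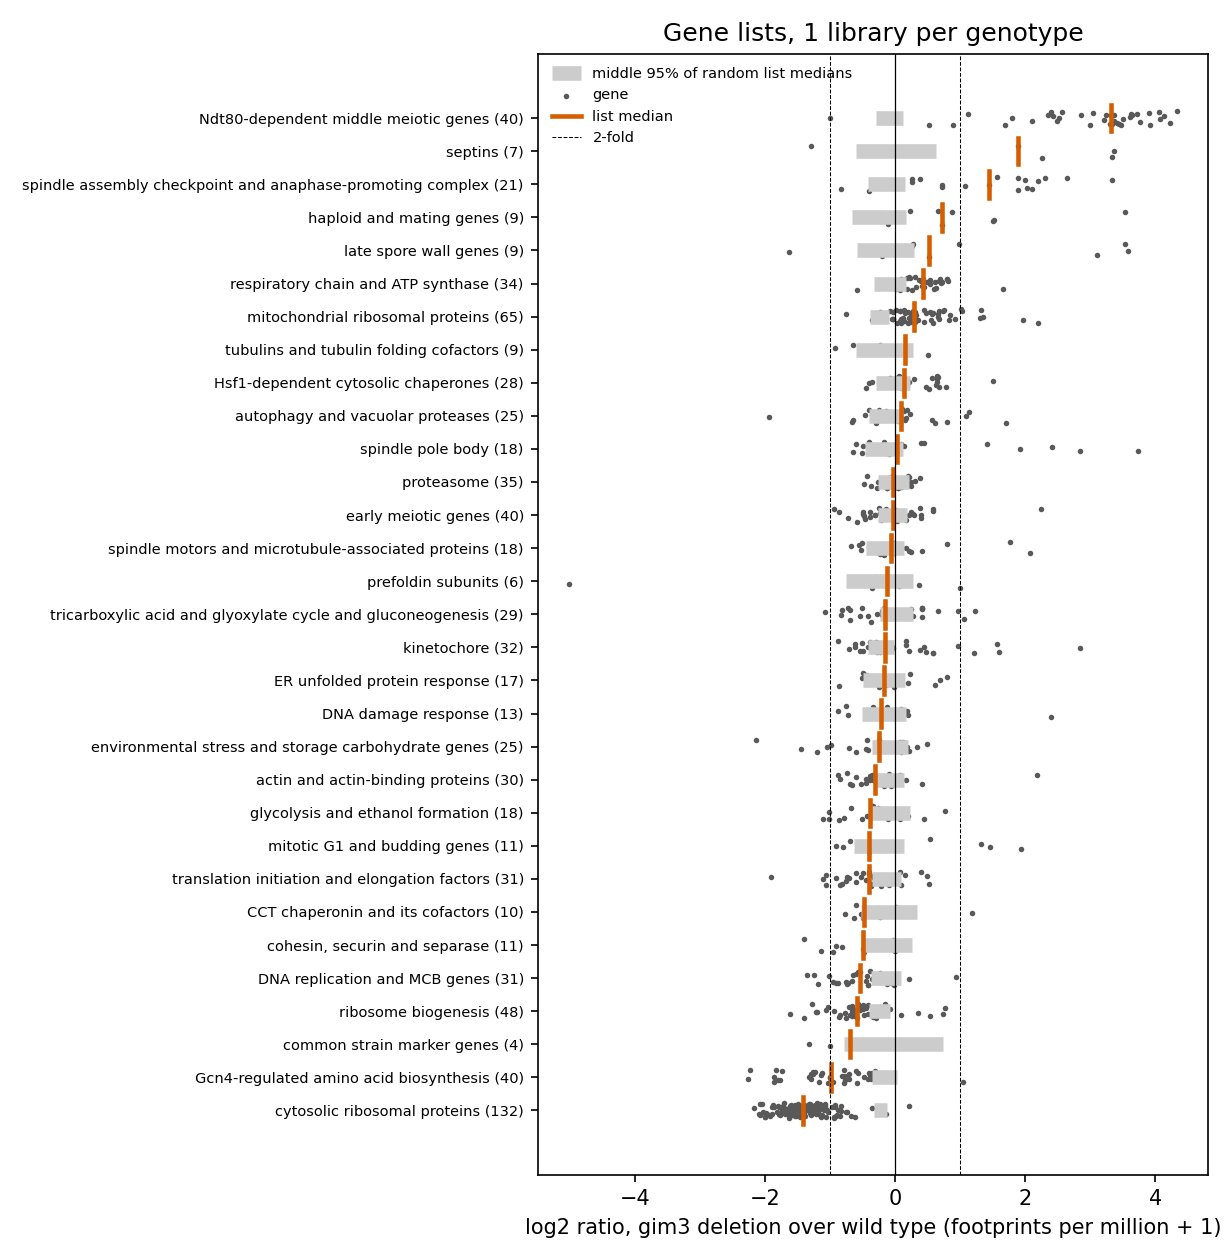
Log2 ratio of RPM plus 1, gim3 deletion over wild type (x axis), for the measured members of the 31 gene lists with at least 3 of them (number in parentheses). Points are genes, orange bars list medians, grey bars the central 95% of medians of 10000 random lists matched on expression, and dashed lines 2-fold; the middle meiotic list has the highest median, 3.32, and the cytosolic ribosomal protein list the lowest, -1.42.

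Among genes of chromosome segregation, the subject of the study, the anaphase-promoting complex stood apart. The list of this ubiquitin ligase and of the spindle assembly checkpoint had 12 of 21 members at least 2-fold higher, 0 lower and a median log2 ratio of 1.45, reached by 0 of 10000 random lists. CDC20, its activator, was 10.4-fold higher, CDC26 6.37-fold, APC2 5.08-fold and CDC16 4.02-fold, and 9 of the 13 subunits were at least 2-fold higher. The checkpoint kinase MPS1 was 3.72-fold higher, while BUB1, MAD1, MAD2 and MAD3 were within 2-fold and BUB3 was lowest with a log2 ratio of -0.83.

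Structural parts of the spindle differed in a few members only. In the spindle pole body list 5 of 18 were at least 2-fold higher and the median, 0.03, was at percentile 92.6. These included SPC42 at 7.28-fold and CNM67 at 5.34-fold, both core components, and ADY4, a meiosis-specific component, at 15.2-fold, and TUB4 was lowest at -0.66. In the kinetochore list 4 of 32 were higher, led by NDC80 at 7.52-fold (6.97 to 8.12), with SGO1, the protector of cohesin, at 3.06-fold, and CTF3 was lowest at -0.87. Its median of -0.16 was at percentile 74.7. Among 18 motors and microtubule-associated proteins, STU2 was 4.25-fold and ASE1 3.51-fold higher, CIN8 had a ratio of 1.33, BIK1 was lowest at -0.67, and the median of -0.07 was at percentile 76.1. The kinetochore and motor medians both become positive when centred, and the list means were positive too, 0.12 and 0.13. All 9 measured tubulins and tubulin cofactors were within 2-fold. TUB2, beta-tubulin, had a ratio of 1.42 (1.40 to 1.44), and the alpha-tubulins TUB1 and TUB3 had ratios of 1.14 and 1.16. The value of TUB3 is uncertain because it overlaps another annotated gene. ALF1, a tubulin cofactor that lies 4 places from GIM3 on the chromosome, had a log2 ratio of -0.92. The list median was 0.15, at percentile 92.8, and the list mean was -0.06. Cohesin, securin and separase genes had a median of -0.49, at percentile 3.39. PDS5 was 2.66-fold and IRR1 2.22-fold lower, while the securin PDS1 had a ratio of 0.973 that turns to higher once centred, and SCC4 the highest log2 ratio, 0.09. Septins had 4 of 7 members higher and 1 lower, with a median of 1.89 that 7 of 10000 random lists reached and a mean of 1.26. SPR3 and SPR28, which also belong to the middle list, were 10.3-fold and 10.1-fold higher. Of the 5 septins outside the middle list, CDC10 was 4.80-fold and CDC3 3.70-fold higher, and SHS1 was 2.65-fold lower. CDC11 and CDC12 had log2 ratios of -0.49 and -0.22. The middle value of these 5 was that of CDC12, near the median gene at -0.20, so the high list median depends on the overlap.

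Most cytosolic ribosomal protein genes were lower in the gim3 deletion library. Of 132 cytosolic ribosomal protein genes 113 were at least 2-fold lower, 19 were within 2-fold and 0 were higher, with a median log2 ratio of -1.42, or 2.68-fold lower. It was 1.22 below the median gene, and 0 of 10000 random lists were as low. RPS3 was the lowest at 4.60-fold, RPL30 was 4.46-fold lower, and RPS28B was the highest with a log2 ratio of 0.21. Together they took 1.38% of footprints in the wild-type library and 0.524% in the gim3 deletion library. Many of these genes have a near-identical second copy, so single values of copies are uncertain. The 19 measured genes with no such copy had a median of -1.63. Ribosome biogenesis genes had a median of -0.58, with 7 of 48 at least 2-fold lower and 0 of 10000 random lists as low. NSR1, a nucleolar protein, was 3.40-fold lower, and DBP3 was the highest at 0.77. Translation factors had a median of -0.41 at percentile 0.795, or 2.67 among unmatched random lists, inside the central range. The median was -0.20 when centred, 27 of 31 were within 2-fold and 4 were lower, with YEF3, an elongation factor, at 3.76-fold lower and TIF11 the highest at 0.53.

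Amino acid biosynthesis genes under Gcn4, the activator of the starvation response, were divided between lower and within 2-fold. Of 40 measured members 19 were at least 2-fold lower and 1 higher, with a median log2 ratio of -0.99 that 0 of 10000 random lists matched. GCN4 itself was 5.28-fold lower (4.50 to 6.23), ASN1, an asparagine synthetase, was 4.88-fold lower, ARG1 3.35-fold lower and ILV2 3.49-fold lower, and SER33 was 2.08-fold higher. Mitochondrial ribosomal protein genes had a median of 0.29, which 0 of 10000 random lists reached, with 7 of 65 at least 2-fold higher and 0 lower. MRPS17 was 4.71-fold higher and MRPL8 was lowest at -0.76. Genes of the respiratory chain and the ATP synthase had a median of 0.42 at percentile 99.98, with CYC1, a cytochrome c, 3.18-fold higher and COR1 lowest at -0.58, and 33 of 34 within 2-fold. Removing a trend on gene length lowered this median to 0.23.

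Folding and degradation genes mostly lay within 2-fold. All 8 CCT subunits had log2 ratios between -0.76 and 0.01. The median of the list of CCT and its cofactors, -0.48, was at percentile 3.97, with CCT6 the lowest. Of 28 genes listed as Hsf1-dependent cytosolic chaperones only HSP26, a small heat shock protein, passed 2-fold, at 2.86-fold higher. SSA3, an Hsp70 gene outside the list, was 3.59-fold higher, with 1845 RPM in the wild-type library and 6621 in the gim3 deletion library. It was picked after its value was seen. The list also holds mitochondrial chaperones, so its median is not one of cytosolic chaperones alone. Of these, HSP60, HSP10 and HSP78 had log2 ratios of 0.65, 0.64 and 0.64, and SSC1 and MDJ1 -0.05 and -0.01. SSA4, an inducible Hsp70, was 1.72-fold higher, HSP104, the disaggregase, had a ratio of 0.949 that turns to higher once centred, SSA2 was lowest at -0.45, and the median of 0.14 was at percentile 91.6. Genes of the unfolded protein response of the endoplasmic reticulum ran from MPD1 at -0.87 to KAR2 at 0.79, with 0 of 17 beyond 2-fold and a median of -0.17 at percentile 53.4. All 35 proteasome genes were within 2-fold, from RPN8 at -0.48 to SEM1 at 0.39, with a median of -0.03 at percentile 53.9, and RPN4, their activator, had a ratio of 1.13. The medians of these last 2 lists and of the prefoldin list, -0.13 at percentile 70.7, become positive when centred. The prefoldin list includes the deleted gene itself, GIM3, at -5.02.

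Of the actin genes 29 of 30 were within 2-fold and the median was -0.31 at percentile 3.80. ACT1 was 1.31-fold lower (1.30 to 1.33), ABP1 was lowest at -0.88, and BNR1, a formin, was 4.57-fold higher. The 29 genes of the tricarboxylic acid and glyoxylate cycles and gluconeogenesis ran from ICL1, isocitrate lyase, 2.11-fold lower, to MDH1, mitochondrial malate dehydrogenase, 2.35-fold higher. Their median was -0.16 at percentile 10.5, and it becomes positive when centred. Glycolysis genes had a median of -0.38 at percentile 3.32, with TDH3 2.16-fold lower and TDH2 highest at 0.76, though the TDH genes are near-identical copies. Autophagy and vacuolar protease genes had a median of 0.09 at percentile 95.6, from CPS1, a carboxypeptidase, 3.87-fold lower, to ATG3 3.29-fold higher. Stress and storage carbohydrate genes had a median of -0.25 at percentile 15.3, with 4 of 25 lower, among them YGP1 at 4.46-fold, and GSY1 highest at 0.50. DNA damage genes had a median of -0.22 at percentile 43.9, with DIN7, a nuclease, 5.55-fold higher and RNR2 lowest at -0.89.

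Lists of genes that mark other cell states were examined for cells outside the programme. Mitotic G1 and budding genes were mostly scarce, with 11 of 22 measured. Their median was -0.40 at percentile 22.6, the list mean was 0.11, and SWE1 was lowest at -0.92. Haploid and mating genes had 9 of 21 measured and a median of 0.72 at percentile 99.99, which was 0.42 with no filter. STE18, a G-protein subunit of the mating pathway, was 12.7-fold higher, STE4 was 2.94-fold and FUS2 3.20-fold higher, and RME1, a repressor of meiosis, was lowest at -0.24. STE18, FUS2 and STE5 stood at 9.77, 5.84 and 9.52 RPM in the wild-type library and passed the filter only through the other library. MFA2, MFA1 and STE2 were below the filter, at 1.72, 1.65 and 1.00 RPM in the gim3 deletion library and less in the wild-type library. The percentile therefore does not show cells outside the programme. Together this list took 0.0138% of footprints in the wild-type library and 0.0337% in the gim3 deletion library. Of the common strain markers, ARG4 was 2.52-fold and LYS2 2.01-fold lower and ADE2 was highest at -0.06, positive when centred, with a list median of -0.69 at percentile 4.03, which was -0.06 with no filter. HIS3 and LEU2 had 0 reads in both libraries, which allows up to 0.0742 RPM in the wild-type library and 0.108 in the gim3 deletion library (3 reads).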

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

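No test of an explanation is reported in this part. The 86 rows without a gene name held reads in data outside the comparisons, and their sum in the gim3 deletion library was slightly above that in the wild-type library, which serves as the control. They held 1235 RPM in the gim3 deletion library and 1211 in the wild-type library, a ratio of 1.02 (exact 95% interval 1.01 to 1.03). The row with the most reads stood at 543 in the wild-type library and 534 in the gim3 deletion library, and 8 of the rows had a mean of at least 10.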

How the results depend on the processing

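The exact binomial test, scaling without the middle list and the genes with no A or B copy were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because each genotype had 1 library, and for the same reason no library could be left out. The number of genes at least 2-fold higher, 312, went to 588 at a 1.5-fold threshold and to 133 at 4-fold. The number lower, 418, went to 1110 and 34 at these thresholds, to 256 when centred on the median gene, to 269 with trimmed-mean scaling and to 253 with a mean of at least 50. Higher genes made up 42.7% of the calls in the deposited scaling, 61.4% when centred and 59.5% with trimmed-mean scaling. The median of the middle list, 3.32, was 3.51 when centred and 3.48 with trimmed-mean scaling. That of the ribosomal protein genes, -1.42, was -1.27 with a pseudocount of 5, -1.22 when centred, -1.25 with trimmed-mean scaling and -1.63 for genes with no A or B copy. That of the early genes, -0.04, was 0.17 when centred and 0.14 with trimmed-mean scaling. The log2 ratio of GIM3, -5.02, was -7.40 with a pseudocount of 0.1. Thresholds and filters change counts by construction. Centring and trimmed-mean scaling use 1 factor per library and move all genes nearly alike. They took the median gene from -0.20 to 0 and to -0.03. A larger pseudocount draws log2 ratios towards 0 and a smaller one does so less, mostly in low genes. Why the ribosomal protein genes with no A or B copy lay lower was not tested. Counted together were the medians of the other lists under the alternatives and the percentiles of all 31 lists fixed beforehand without matching on expression. Of these values 430 stayed within their range or on the same side, and 30 moved. Single genes other than GIM3 are not among these values. Of the 31 lists fixed beforehand, the medians of 7 changed sign when centred, and 0 of these lay outside the random range. Without matching on expression, 28 of 31 lists stayed on the same side of the random range's ends, though percentiles inside it moved widely (early genes 56.6 to 94.8, proteasome 53.9 to 94.0), and the chaperone list (percentile 99.6) and the autophagy list (98.1) came to lie above the random range and the translation factor list (2.67) just inside it. At this depth the upper end of the counting interval of the fold was 1.13 times the lower end for the median gene and 14.2 times for GIM3, the widest.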

Other observations

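Several further gene groups were examined with lists written after the data had been seen, so their counts are no independent evidence of direction. A list of nitrogen catabolite repressed genes covers uptake and breakdown of poor nitrogen sources. It also holds regulators and the enzymes of glutamate and glutamine synthesis GDH1, GDH3, GLT1 and GLN1. In the gim3 deletion library 23 of its 28 measured members were at least 2-fold lower and 0 higher. The median log2 ratio was -1.80, which 0 of 10000 random lists matched. The list holds 10 of the 12 lowest genes of the comparison, GIM3 aside, which had been seen when the list was written. Beyond the genes already named, AGP1, an amino acid permease, was 4.76-fold lower, GLT1, glutamate synthase, 4.63-fold, GLN1, glutamine synthetase, 3.37-fold, and the regulators DAL80 and GAT1 3.11-fold and 2.09-fold. DAL4 had the highest ratio of the list, -0.08, positive when centred. Fatty acid synthesis was lower in 5 of 9 members, with a median of -1.12. FAS1 and FAS2, the fatty acid synthase subunits, were 5.17-fold and 4.40-fold lower, ACC1, acetyl-CoA carboxylase, 3.91-fold and OLE1, the desaturase, 3.50-fold, while the elongase ELO3 had a log2 ratio of 0.54.

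Iron uptake genes were at least 2-fold lower in 5 of 14 members, among them FIT3 at 4.37-fold and FET3 at 2.73-fold, and ATX1, a copper chaperone, was 2.19-fold higher. Their median was -0.79. Subunits of the vacuolar ATPase had a median of -0.73 with 5 of 15 lower, from VMA13 at 3.21-fold lower to VMA9 at -0.07, positive when centred. Other lists of this kind lay inside the central range of random lists. These were ergosterol synthesis (median -0.39, percentile 3.41), aminoacyl-tRNA synthetases (-0.37, percentile 5.91), peroxisome and fatty acid oxidation genes (-0.26, percentile 34.6) and the nuclear pore (-0.15, percentile 57.4, positive when centred). FLO11, a cell surface flocculin, had the most footprints of any gene in the wild-type library, 28689 RPM, and 8164 in the gim3 deletion library. The mitochondrial endonuclease row SCEI held 10028 and 13382 RPM, while each of 8 other protein genes of the mitochondrial genome, such as COX1 and COB, had at most 0.297 in the wild-type library and was listed at 0 in the gim3 deletion library. Whether the reads of the SCEI row come from translation of that gene is doubtful and was not tested. The row stayed in the comparison and in the scaling. Of the genes at least 2-fold apart, 222 of those higher and 256 of those lower belong to no list fixed before the data were examined.

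For 3 patterns technical explanations were set against the tables. The tests of gene length and of the neighbourhood of GIM3 were fixed before their results were seen, and the other 6 tests only afterwards.

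For the higher footprints of Ndt80-dependent middle genes in the gim3 deletion library, the lowest list median over 4 other scalings was 3.30. Each of these scalings uses 1 factor per library and moves all genes nearly alike, so it could hardly have removed a median of 3.32. What argues against such a factor as the source is that the list median lay 3.52 above the median gene. An exchange of the 2 labels is excluded by GIM3 itself, at 0.108 RPM in the library labelled gim3 deletion. An expectation for a gim3 deletion culture further along in meiosis was lower replication and lower early genes as well. It was met in part only, since replication genes were lower (median log2 ratio -0.54) and early genes were not (-0.04, and 0.17 when centred). Because it was written after these values were seen, this outcome speaks neither for nor against a difference in stage. Whether the difference in middle genes follows from the deletion or from how these 2 cultures entered meiosis cannot be told apart, because each genotype was sampled once.

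The lower footprints of cytosolic ribosomal protein genes are not explained by reads shared between copies, since the members with no second copy had a median of -1.63. After removal of a trend on gene length the median was -1.44. The lengths used include introns, so a trend on coding length is not excluded. The share of reads that middle genes took does not explain the lower footprints either, since it would move all other genes alike. The list median was still -1.22 when centred on the median gene. Lower mRNA levels and lower translation of these genes both remain possible, as does a difference in stage, and footprints alone do not separate them.

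YCK2, next to GIM3, had a log2 ratio of 2.21, and 116 genes had a higher one. A change along the whole neighbourhood, such as an extra copy of the region, is argued against by the other 8 measured genes within 5 places of GIM3, whose median was -0.54 and whose highest was 0.23. A local effect of the deletion cassette on YCK2 may account for the value, and so could a rise of YCK2 with the middle programme. These cannot be told apart, since no library with another deletion at the same stage was analysed here.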
